A study of Mus musculus with 52 samples.

How the data were processed

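RNA was measured by sequencing in 52 libraries from mice that carry human CD40 and tumors of MC38-CEACAM5, a colon carcinoma cell line that expresses CEACAM5, treated with vehicle, with a CD40 antibody (CD40 mAb) or with ATOR-4066, a bispecific antibody against CD40 and CEACAM5. The libraries come from 4 materials, namely blood, lymph node, whole tumor and CD45+Ly6G- cells sorted from tumors, and each library was assigned to its material and treatment from its title and labels. Blood, lymph node and tumor libraries that share an animal number come from the same animal, as read from the titles; the sorted cells carry other animal numbers. All 52 columns of the deposited table were mapped to a labelled sample, and none was left out of the comparisons.

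The deposited table holds estimated counts per gene, not scaled for depth or gene length, which salmon merged over samples, per the name of the deposited table. Per the submitters' processing notes, reads were processed with STAR, whose version is given as 5.1, on genome build GRCm38. Per the labels' protocols, polyA RNA was extracted and made into libraries with a stranded mRNA kit. The quantification settings and the gene annotation are not given in the sources used here. Of the cells of the deposited table, 11 percent hold fractional counts, and these were rounded to whole numbers. The table has 57010 genes, of which 52081 have an identifier in GENCODE vM21 of GRCm38, the source of the coordinates printed here. There are 150 symbols carried by more than one identifier, and genes were tested by identifier. Total counts ranged from 47.4 to 67.6 M in tumor (median 52.5 M), from 30.2 to 47.4 M in sorted cells (median 39.9 M), from 46.3 to 138.5 M in lymph node (median 51.8 M) and from 33.5 to 44.1 M in blood (median 36.4 M). In blood, haemoglobin genes took 69.8 to 88.2 percent of counts, which leaves fewer counts for the other genes than the totals show. In the other materials they took at most 0.602 percent.

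Within each material the 3 treatments were fitted together with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr (count minimum 10, total 15), libraries were scaled with TMM factors, and treatments were compared with the quasi-likelihood F test with robust dispersion, adjusted by the Benjamini-Hochberg method over all genes tested in that comparison. A gene is called at an adjusted p under 0.05. Errors of log2 changes are standard errors (SE), and levels are CPM on TMM-scaled library sizes with their standard deviation (SD). Unless another test is named, every adjusted p of a gene is from this edgeR test. The 12 comparisons are ATOR-4066 against vehicle, CD40 mAb against vehicle and ATOR-4066 against CD40 mAb in each of the 4 materials.

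The comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule takes, from the called genes with an average log2-CPM of at least 1 and without predicted genes, pseudogenes or receptor segments, the largest changes in each direction (10 higher and 10 lower, or 10 higher and 5 lower for CD40 mAb against vehicle). Where fewer than 5 genes pass, it takes the 5 of smallest p as values only. It adds the 4 members of smallest p of each list, and Cd40, Ptprc, Ly6g and Cd8a in every material where they were measured. Genes named under this rule are a part of those it selects. A result for 1 of the genes it selects is not reported here.

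There were 29 gene lists: interferon-gamma-induced genes, type I interferon-induced genes, MHC class I presentation, MHC class II presentation, NF-kappaB target genes, dendritic cell maturation and costimulation, inflammatory cytokines and chemokines, cytotoxic effector genes, T cell checkpoint and exhaustion genes, proliferation genes, hypoxia and glycolysis genes, plasma cell and germinal center genes, immediate early and heat shock genes, and markers of T cells, regulatory T cells, NK cells, B cells, macrophages, monocytes, conventional dendritic cells, plasmacytoid dendritic cells, neutrophils, eosinophils with basophils and mast cells, erythroid cells, platelets and megakaryocytes, tumor epithelium, fibroblasts and matrix, endothelium, and skeletal muscle with skin and fat. Of their members Ddx58 and Ahsp were not found by symbol, and Aldoa is carried by a pair of identifiers. Each list was tested with camera of limma 3.58.1 on log2-CPM values, which asks whether a list's genes rank higher or lower than the other genes, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. The same test with a correlation estimated from the data is given beside it. Counts of called members are given over all genes tested and adjusted over the list alone.

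Differences of a drug effect between tumor, lymph node and blood were tested as interactions with voomLmFit (edgeR and limma) on all libraries of these materials, with sample weights by tissue and the animal as a random block. Fold changes of both drugs against the shared vehicle libraries were compared with those of 20 simulations of unchanged groups that shared simulated vehicle libraries. They were also compared with the overlap of independent lists, and with the vehicle libraries divided in 2 parts. Each simulation drew all libraries, vehicle included, from a common mean per gene, independently between genes. Alternatives were DESeq2-type size factors in edgeR, DESeq2 1.42.0, limma-voom with sample quality weights, no filter on low counts, a stricter filter of 50 counts, haemoglobin and receptor segment genes left out, only the groups compared, the replicate number as a block, and each library left out in turn. For the interactions they were edgeR without the animal block and voomLmFit without sample weights. After the data were seen, fits without the library labelled tumor ATOR-4066 3 and the library labelled lymph node vehicle 3 were added, because these carried the profile of another tissue, and so was a fit of blood with scaling to the total count alone.

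Each test was tested on simulated data in which 200 genes were changed, 100 of them by 2-fold and 100 by 4-fold, with counts drawn at the means and library sizes of the real samples. Recovery of 2-fold and of 4-fold changes was, in percent, 21 and 55 for tumor ATOR-4066 against vehicle, 19 and 57 for tumor CD40 mAb against vehicle, and 25 and 67 for tumor ATOR-4066 against CD40 mAb, each over 18670 genes. In sorted cells it was 17 and 61, 30 and 65, and 22 and 48 for the same comparisons over 16667 genes. In lymph node it was 35 and 73, 38 and 61, and 21 and 66 over 18763 genes, and in blood 65 and 94, 67 and 97, and 60 and 89 over 12184 genes. For the simulated interaction it was 34 and 72 over 20473 genes. There the changed genes were drawn only from those with higher counts in vehicle tumor, and the libraries of an animal were drawn independently. These values are therefore not comparable with those within tissues. No read files were used here, and tumor sizes, survival and flow cytometry were not analysed here.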

Results

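Gene expression was measured by RNA sequencing in 52 libraries from hCD40tg mice, which carry human CD40, with MC38-CEACAM5 tumors. The mice received vehicle, CD40 mAb (an antibody against CD40, a receptor that activates dendritic cells, macrophages and B cells) or ATOR-4066, a bispecific antibody against CD40 and the tumor antigen CEACAM5. Whole tumor gave 5 ATOR-4066, 5 CD40 mAb and 4 vehicle libraries, sorted CD45+Ly6G- tumor cells gave 3, 3 and 4, lymph node gave 5, 4 and 5, and blood gave 4, 5 and 5. Median total counts per library were 52.5 M in tumor, 39.9 M in sorted cells, 51.8 M in lymph node and 36.4 M in blood. Mouse Cd40 (ENSMUSG00000017652, chromosome 2, 165055627 to 165072948, GRCm38) passed the test in none of the 12 comparisons. Its level was 134 ± 18.9 CPM in sorted vehicle cells (SD, n = 4), 37.6 ± 4.43 CPM in vehicle tumor (n = 4), 61.3 ± 4.24 CPM in vehicle lymph node (n = 5) and 3.50 ± 0.398 CPM in vehicle blood (n = 5). The human transgene was not analysed here. A pair of libraries carried the profile of another tissue than their label. In the library labelled lymph node vehicle 3, Ptprc (CD45, carried by leukocytes) was at 218 CPM against 812 to 1050 CPM in the other vehicle lymph nodes, and B cell markers had a mean log2-CPM of -0.46 against 7.77 to 8.45. In the library labelled tumor ATOR-4066 3, B cell markers were at 8.07 against 0.64 to 2.49 in the other ATOR-4066 tumors. Both stayed in the fits, and values without them are given where they matter.

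In the sorted tumor leukocytes, ATOR-4066 against vehicle asks what the bispecific antibody changed in the immune cells of the tumor. T cell genes rose. Of 18 T cell markers 17 were higher, and 18 adjusted over the list alone, with a median log2 change of 1.83 (camera adjusted p = 3.21e-13, adjusted p = 0.481 with an estimated correlation). Cd3e, a chain of the T cell receptor complex (ENSMUSG00000032093, chromosome 9, 44998740 to 45009627), rose from 80.1 ± 14.1 CPM (SD, n = 4) to 282 ± 132 CPM (n = 3), a log2 change of 1.81 ± 0.30 (SE, adjusted p = 0.0108). Cd4, the helper T cell coreceptor, rose by 2.33 ± 0.39 (adjusted p = 0.0108), and Cd8a, the cytotoxic T cell coreceptor, by 1.52 ± 0.41 (adjusted p = 0.0403, above every vehicle library in 2 of 3 libraries). Proliferation genes rose as well, 17 of 20 over all genes and 20 adjusted over the list alone (median 1.74, camera adjusted p = 3.58e-12, adjusted p = 0.481 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 2.53 ± 0.37 and Top2a, a topoisomerase of dividing cells, by 2.07 ± 0.37. Type I interferon-induced genes fell, 8 of 19 over all genes and 17 adjusted over the list alone (median -1.51, camera adjusted p = 9.16e-10, adjusted p = 0.481 with an estimated correlation). The antiviral GTPase gene Mx1 dropped by 2.44 ± 0.41 on the log2 scale, from 472 ± 103 to 86.9 ± 42.7 CPM (adjusted p = 0.0108, lower in 3 of 3 libraries than in every vehicle library).

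Some genes of myeloid cells fell in the same cells. Cx3cr1, the fractalkine receptor of patrolling monocytes and macrophages (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), dropped by 2.94 ± 0.43 (SE), from 367 ± 51.4 CPM (SD, n = 4) to 47.8 ± 27.7 CPM (n = 3, adjusted p = 0.00829). Ccr2, the receptor that brings monocytes into tissue, dropped by 1.04 ± 0.21, Clec9a, a marker of cross-presenting dendritic cells, by 2.52 ± 0.49, and the macrophage genes Trem2 and C1qa by 2.08 ± 0.44 and 2.18 ± 0.57. Of the lists, monocyte markers fell with 2 of 13 members lower and 4 adjusted over the list alone (median -1.08, camera adjusted p = 0.00279), and macrophage markers with 4 of 18 lower and 1 higher, 5 and 1 adjusted over the list alone (median -0.79, camera adjusted p = 0.0112). Both had an adjusted p = 0.481 with an estimated correlation. The member that rose was Gpnmb, by 2.24 ± 0.47. Conventional dendritic cell markers (5 of 15 lower, median -0.56, camera adjusted p = 0.0133), plasmacytoid dendritic cell markers (4 of 9 lower and 1 higher, median -1.53, 0.00682), MHC class II genes (1 of 11 lower, Ciita, their master regulator, median -0.86, 0.00812) and fibroblast and matrix genes (4 of 16 lower, median -2.25, 0.000375) also ranked lower. Each had an adjusted p = 0.481 with an estimated correlation. Adjusted over the list alone, 6 conventional and 6 plasmacytoid dendritic cell markers were lower and 1 of each higher, and 9 fibroblast and 0 MHC class II genes were lower. Without ATOR-4066 9 the medians were -0.34 for macrophage, -0.71 for monocyte and -0.29 for conventional dendritic cell markers. Without ATOR-4066 10 they were -1.49, -1.32 and -0.54.

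A part of the inflammatory and effector genes rose with ATOR-4066 in the sorted cells. Of 18 inflammatory cytokines and chemokines 6 rose and 1 fell, 9 and 4 adjusted over the list alone (median 0.73, camera adjusted p = 0.0413, adjusted p = 0.481 with an estimated correlation). Cxcl1, a chemokine that attracts neutrophils (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), rose by 4.08 ± 0.58 to 6.96 ± 0.92 CPM (SD, n = 3), and the prostaglandin synthase gene Ptgs2 by 2.92 ± 0.46 to 131 ± 76.7 CPM (adjusted p = 0.00739 and 0.0102). Nfkbia and Tnfaip3, feedback inhibitors of NF-kappaB, rose by 1.72 ± 0.19 and 2.32 ± 0.39, while the NF-kappaB list as a whole did not pass (4 of 15 higher over all genes, 4 higher and 2 lower adjusted over the list alone, median 0.10, camera adjusted p = 0.109). Cytotoxic effector genes ranked higher (3 of 17 called, 4 adjusted over the list alone, median 0.82, camera adjusted p = 0.0201, adjusted p = 0.481 with an estimated correlation). In that list the T cell chemokine gene Ccl5 rose by 1.73 ± 0.24, the granzyme gene Gzmk by 2.98 ± 0.57 and Ifng, which encodes interferon-gamma, by 1.48 ± 0.38. Nos2, inducible nitric oxide synthase, rose by 3.69 ± 0.68 although the interferon-gamma-induced list around it ranked lower (median -0.53, 1 of 21 called over all genes and over the list alone, camera adjusted p = 0.00484, adjusted p = 0.481 with an estimated correlation). Hypoxia genes (4 of 17 higher, 6 adjusted over the list alone, median 0.56, camera adjusted p = 0.00279) and immediate early and heat shock genes (6 of 15, 7 adjusted over the list alone, median 0.58, 0.00484) ranked higher, each with an adjusted p = 0.481 with an estimated correlation. The hypoxia median was 0.34 without ATOR-4066 10, and the interferon-gamma-induced median was -1.04 without that library and -0.29 without ATOR-4066 9. The checkpoint list did not pass (camera adjusted p = 0.0807), although the T cell costimulator Icos rose by 1.79 ± 0.37 and the checkpoint gene Ctla4 by 1.84 ± 0.51 (adjusted p = 0.0177 and 0.0453). Among the largest changes were Il21, a cytokine of helper T cells (5.01 ± 1.06), and Gatm, an enzyme of creatine synthesis, which dropped by 3.99 ± 0.55.

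Over all genes, edgeR called 1977 of 16667 genes between ATOR-4066 and vehicle in sorted cells, 1126 higher and 851 lower. The count was 931, 823 and 627 without vehicle 6, 9 and 10, 701 without ATOR-4066 6, 1017 without ATOR-4066 9, and 4484 with the voom sample weights. B cell markers had a median of 2.95 (3 of 14 called, 8 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.481 with an estimated correlation) that fell to -0.01 without ATOR-4066 9, whose B cell level was 5.54 against 1.71 and 0.92 in the other ATOR-4066 libraries. Erythroid markers had a median of 3.01 (1 of 8 called, 7 adjusted over the list alone, camera adjusted p = 0.0641), and -1.43 without ATOR-4066 6, whose erythroid level was 7.87 against 2.98 and 4.13. Eosinophil, basophil and mast cell markers ranked higher (1 of 10 called, median 0.52, camera adjusted p = 0.0112, adjusted p = 0.481 with an estimated correlation). That median was 0.12 without vehicle 6 and 2.13 without vehicle 7. Lists that did not pass were plasma cell genes (median 0.94, camera adjusted p = 0.0503), dendritic cell maturation genes (0.75, 0.0641), regulatory T cell markers (0.53, 0.0708), MHC class I genes (-0.23, 0.0708), NK cell markers (-0.64, 0.0938), endothelial markers (-0.73, 0.105), neutrophil markers (0.93, 0.182), tumor epithelial markers (0.15, 0.344), platelet markers (0.16, 0.373) and skeletal muscle, skin and fat genes (-0.26, 0.783).

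**Figure D1:**
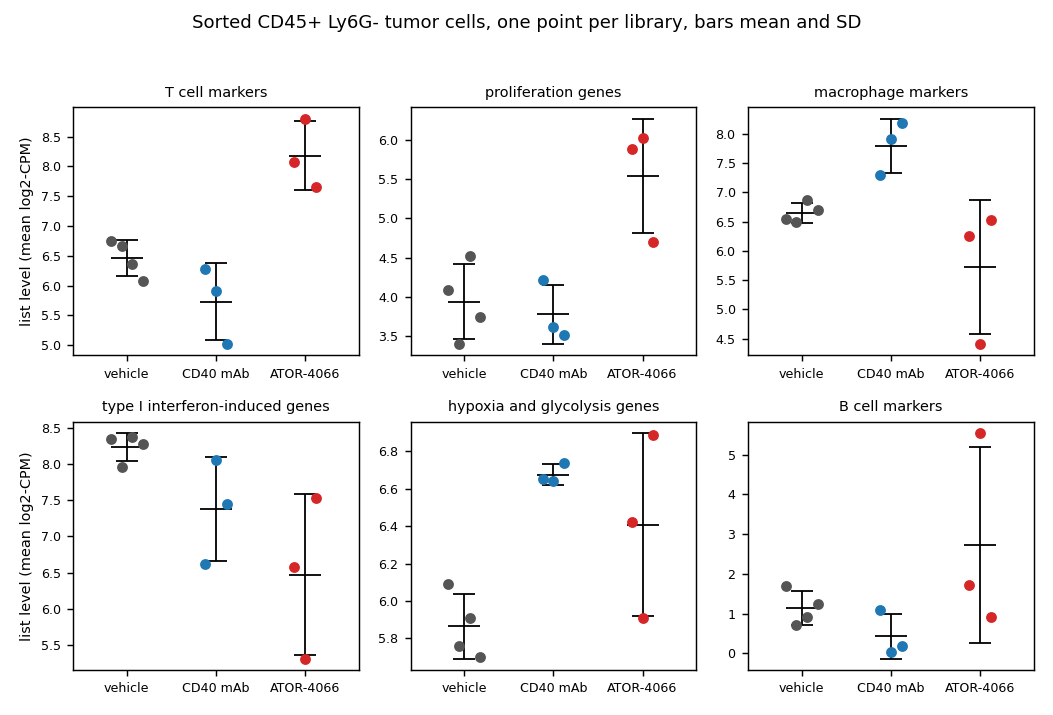
Mean log2-CPM of 6 gene lists in each sorted CD45+Ly6G- library by treatment, 1 point per library, with bars for the mean and SD of each group. T cell markers lie at 7.66 to 8.80 in the 3 ATOR-4066 libraries, above the 6.07 to 6.74 of the 4 vehicle libraries.

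With CD40 mAb against vehicle, fewer genes were called in the sorted cells. Cxcl1 and Cxcl2, chemokines that attract neutrophils, rose, Cxcl1 by 5.21 ± 0.60 (SE) to 15.3 ± 8.07 CPM (SD, n = 3), from 0.403 ± 0.276 CPM in vehicle (n = 4), and Cxcl2 by 3.73 ± 0.67 (adjusted p = 0.00992 and 0.0416, above every vehicle library in 3 of 3). The inflammatory list as a whole did not pass (2 of 18 higher, 5 adjusted over the list alone, median 0.19, camera adjusted p = 0.0623). Folr2, a folate receptor of macrophages (ENSMUSG00000032725, chromosome 7, 101839988 to 101857194), rose by 4.21 ± 0.56 (4.24 ± 0.698 to 78.5 ± 47.3 CPM, adjusted p = 0.0191) and Lpl, lipoprotein lipase, by 4.35 ± 0.53 (adjusted p = 0.0125). All 18 macrophage markers had positive changes, 1 of them called and 6 adjusted over the list alone (median 0.78, camera adjusted p = 4.72e-05, adjusted p = 0.67 with an estimated correlation). Mrc1 and Arg1, markers of alternatively activated macrophages, had changes of 2.31 ± 0.54 and 1.97 ± 0.48 that did not pass (adjusted p = 0.0675 and 0.0731). Hypoxia and glycolysis genes rose, 3 of 17 over all genes and 13 adjusted over the list alone (median 0.90, camera adjusted p = 1.66e-08, adjusted p = 0.392 with an estimated correlation). In that list the oxygen sensor Egln3 rose by 1.94 ± 0.33 and Pdk1 by 0.69 ± 0.14. T cell markers ranked lower (0 of 18 called by edgeR, 17 of 18 negative, median -0.60, camera adjusted p = 4.72e-05, adjusted p = 0.67 with an estimated correlation). Ikzf2, the transcription factor Helios, fell (-1.40 ± 0.27, adjusted p = 0.0451). Regulatory T cell markers ranked lower as well, with 1 of 7 called and 6 lower and 1 higher adjusted over the list alone (median -1.16, camera adjusted p = 0.00195, adjusted p = 0.67 with an estimated correlation). Immediate early genes (4 of 15 adjusted over the list alone, median 0.50, camera adjusted p = 1.45e-05) ranked higher and type I interferon-induced genes (1 of 19 adjusted over the list alone, 0 positive, median -0.68, camera adjusted p = 0.000327) ranked lower, with adjusted p = 0.0893 and 0.693 with an estimated correlation. edgeR called 182 genes, 89 higher and 93 lower. The count was 22, 15 and 2 without vehicle 6, 9 and 10, 9 without CD40 mAb 6, 13 without CD40 mAb 10, and 1465 by DESeq2. The T cell median was -0.30 without CD40 mAb 10 and -0.92 without CD40 mAb 6, and the type I interferon median -0.35 without CD40 mAb 6 and -1.20 without CD40 mAb 7.

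Set directly against CD40 mAb in sorted cells, ATOR-4066 gave higher T cell genes and lower macrophage genes. All 18 T cell markers were higher (median 2.58, camera adjusted p = 1.91e-18, adjusted p = 0.488 with an estimated correlation). Cd3e was at 282 ± 132 CPM against 42.3 ± 12.2 CPM (SD, n = 3 each), a log2 change of 2.74 ± 0.34 (SE, adjusted p = 0.00868). Cd8a rose by 2.79 ± 0.47 and Cd40lg, the natural ligand of CD40 on helper T cells, by 4.05 ± 0.62. Of 7 regulatory T cell markers 6 rose, 6 and 1 lower adjusted over the list alone (median 1.77, camera adjusted p = 0.000364, adjusted p = 0.488 with an estimated correlation). Foxp3, their lineage factor, rose by 2.16 ± 0.42 and Il2ra by 2.28 ± 0.41. Checkpoint genes rose in 4 of 12 over all genes and in 7 adjusted over the list alone (median 1.27, camera adjusted p = 0.00123, adjusted p = 0.488 with an estimated correlation). These were Icos, Ctla4, Pdcd1 and Lag3, by 2.77 ± 0.42, 2.68 ± 0.58, 1.96 ± 0.37 and 1.43 ± 0.36. Proliferation genes rose in 15 of 20, and in 20 adjusted over the list alone (median 1.99, camera adjusted p = 1.51e-12, adjusted p = 0.488 with an estimated correlation). Macrophage markers fell in 6 of 18, and in 13 adjusted over the list alone (median -1.99, camera adjusted p = 7.75e-09, adjusted p = 0.488 with an estimated correlation). Folr2 had a change of -3.83 ± 0.61, C1qa of -2.67 ± 0.61 and Trem2 of -2.31 ± 0.46. Type I interferon-induced genes ranked lower with 0 of 19 called (median -0.80, camera adjusted p = 0.00039, adjusted p = 0.665 with an estimated correlation). Cytotoxic genes ranked higher with 4 of 17 called, 5 adjusted over the list alone (median 0.72, camera adjusted p = 0.00616, adjusted p = 0.665 with an estimated correlation). Ifng rose by 2.05 ± 0.43 and Ccl5 by 1.54 ± 0.26. edgeR called 1372 genes, 879 higher and 493 lower. The count was 307 without CD40 mAb 7, 105 without CD40 mAb 10, and 530, 579 and 2422 without ATOR-4066 6, 9 and 10. It was 3 when only these groups were fitted. The cytotoxic median was 0.31 without CD40 mAb 10, and the type I interferon median -0.43 without CD40 mAb 7 and -1.44 without ATOR-4066 10. DESeq2 called 2960 genes, 53.2 percent of them higher in place of 64.1 percent. The B cell median of 3.44 was 0.65 without ATOR-4066 9.

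In whole tumor no gene passed, and gene groups are given by their rank and values. With ATOR-4066 against vehicle, genes of inflammation and neutrophils ranked higher. Cxcl3, a neutrophil chemokine (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600), was at 18 ± 20.4 CPM (SD, n = 5) against 0.173 ± 0.0411 CPM (n = 4), a log2 change of 6.69 ± 1.06 (SE, adjusted p = 0.0555), above every vehicle tumor in 5 of 5. The cytokine gene Il6 had a change of 3.03 ± 0.62, the alarmins S100a8 and S100a9 of 4.78 ± 0.94 and 5.36 ± 1.04, and Cx3cr1 of -4 ± 0.78 (each adjusted p = 0.0656, each beyond every vehicle tumor in 5 of 5). Inflammatory genes ranked higher (9 of 18 adjusted over the list alone, 0 over all genes, median 1.28, camera adjusted p = 2.80e-06), as did neutrophil markers (8 higher and 1 lower of 14 adjusted over the list alone, median 2.20, 7.08e-07), each with an adjusted p = 0.626 with an estimated correlation. NF-kappaB targets (7 of 15 adjusted over the list alone, median 0.79, camera adjusted p = 3.94e-05) and dendritic cell maturation genes (10 of 17, median 1.25, 4.51e-05) also ranked higher, each with an adjusted p = 0.685 with an estimated correlation. Without the library labelled tumor ATOR-4066 3, 5 and 0 of these members passed adjusted over the list alone. In these lists Nfkbia had a change of 0.97 ± 0.16 (adjusted p = 0.0555), the costimulator Cd80 of 1.85 ± 0.51 and the dendritic cell chemokine Ccl22 of 2.13 ± 0.59 (adjusted p = 0.0871 and 0.0903). Proliferation genes ranked lower, 0 of 20 adjusted over the list alone (median -0.86, camera adjusted p = 2.80e-06, adjusted p = 0.687 with an estimated correlation), and 11 were lower without that library. Top2a had a change of -1.18 ± 0.41 (adjusted p = 0.131). Hypoxia and glycolysis genes ranked higher (0 of 17 adjusted over the list alone, median 0.92, camera adjusted p = 0.00813, adjusted p = 0.801 with an estimated correlation). So did immediate early and heat shock genes (7 of 15, median 0.32, camera adjusted p = 0.0372, adjusted p = 0.687 with an estimated correlation). T cell markers had a median of 1.77 (0 of 18 adjusted over the list alone, camera adjusted p = 0.00208, adjusted p = 0.801 with an estimated correlation), which was 0.86 without that library. The plasma cell list moved from 3.16 to 0.44 and the B cell list from 4.04 to -0.70 when that library was left out. Type I interferon-induced genes did not pass (median 0.43, camera adjusted p = 0.902), while their median in sorted cells was -1.51. edgeR called 0 of 18670 genes, with 4396 at an unadjusted p under 0.05. DESeq2 called 1773 and limma-voom with sample weights 5043. Without the library labelled tumor ATOR-4066 3 edgeR called 243 (169 higher, 74 lower). Among them were 7 of 13 neutrophil markers and 4 of 18 inflammatory genes.

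CD40 mAb against vehicle in whole tumor ranked erythroid, neutrophil and hypoxia genes higher and proliferation genes lower. Tumor epithelial markers were positive in 13 of 13 but did not pass (median 2.5, camera adjusted p = 0.121). Scaled to the total count, Ptprc ranged from 98.9 to 571.4 CPM among the CD40 mAb tumors, the highest in CD40 mAb 5. Hbb-bs, a beta globin, was at 198 ± 159 CPM (SD, n = 5) against 45.3 ± 16.1 CPM (n = 4), a change of 2.13 ± 0.56 (SE). S100a9 had a change of 3.65 ± 0.95, and neither passed (adjusted p = 0.561 each, above every vehicle tumor in 5 of 5 and 4 of 5). Erythroid markers ranked higher (6 of 9 adjusted over the list alone, median 2.09, camera adjusted p = 1.41e-06, adjusted p = 0.167 with an estimated correlation). Neutrophil markers (4 of 14 adjusted over the list alone, median 1.86, camera adjusted p = 0.000259) and hypoxia genes (0 of 17, median 1.18, 7.84e-05) ranked higher, with adjusted p = 0.89 and 0.996 with an estimated correlation. Proliferation genes ranked lower (0 of 20, median -0.76, camera adjusted p = 2.54e-12, adjusted p = 0.7 with an estimated correlation), with Top2a at -0.93 ± 0.41. Interferon-gamma-induced genes (0 of 21, median -0.39, camera adjusted p = 6.50e-05) and type I interferon-induced genes (0 of 19, median -0.47, 0.000357) ranked lower, each with an adjusted p = 0.996 with an estimated correlation. edgeR called 0 genes, with 1621 at an unadjusted p under 0.05, DESeq2 called 21 and limma-voom with sample weights 1.

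ATOR-4066 against CD40 mAb in whole tumor separated inflammatory and interferon genes from erythroid genes. Il6 was at 2.94 ± 2.29 CPM (SD) against 0.365 ± 0.226 CPM (n = 5 each), a change of 2.99 ± 0.56 (SE, adjusted p = 0.167, above every CD40 mAb tumor in 5 of 5), and Socs3, a feedback inhibitor of cytokine signaling, had a change of 1.21 ± 0.17 (adjusted p = 0.115, 5 of 5). Cd274, the checkpoint ligand PD-L1, was at 256 ± 126 CPM against 75.7 ± 44.7 CPM (change 1.76 ± 0.41, adjusted p = 0.305, 3 of 5). All 18 inflammatory genes were positive, 9 adjusted over the list alone (median 1.11, camera adjusted p = 6.40e-15, adjusted p = 0.0504 with an estimated correlation, and 0.039 without the library labelled tumor ATOR-4066 3). Interferon-gamma-induced genes (2 of 21 adjusted over the list alone, median 0.80, camera adjusted p = 5.36e-12), MHC class I genes (0 of 13, median 0.41, 1.95e-07) and neutrophil markers (5 of 14, median 1.15, 2.59e-06) ranked higher, each with an adjusted p = 0.231 with an estimated correlation. Type I interferon-induced genes ranked higher too (0 of 19 adjusted over the list alone, median 0.97, camera adjusted p = 0.000112, adjusted p = 0.522 with an estimated correlation). Their median was 1.19 without the library labelled tumor ATOR-4066 3, while in sorted cells it was -0.80. NF-kappaB targets (4 of 15 adjusted over the list alone, median 0.55, camera adjusted p = 1.28e-11) and dendritic cell maturation genes (4 of 17, median 0.98, 2.36e-09) ranked higher, each with an adjusted p = 0.161 with an estimated correlation. So did immediate early and heat shock genes (3 of 15, median 0.37, camera adjusted p = 0.000555, adjusted p = 0.177 with an estimated correlation). Without the library labelled tumor ATOR-4066 3 the last of these was 0.039. Then 7 interferon-gamma-induced genes, 2 NF-kappaB targets and 2 dendritic cell maturation genes passed adjusted over the list alone, and the neutrophil median was 1.75. Erythroid markers ranked lower (6 of 9 adjusted over the list alone, median -2.25, camera adjusted p = 4.28e-08, adjusted p = 0.0504 with an estimated correlation), with the heme synthesis gene Alas2 at -2.95 ± 0.63 (adjusted p = 0.27). edgeR called 0 genes, with 1570 at an unadjusted p under 0.05. DESeq2 called 184 and limma-voom with sample weights 449. edgeR called 103 without CD40 mAb 5, 1 without ATOR-4066 5 and 6 without the library labelled tumor ATOR-4066 3. Without the last of these the T cell median of 0.47 became -0.48 and the B cell median of 4.97 became -0.19.

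**Figure D2:**
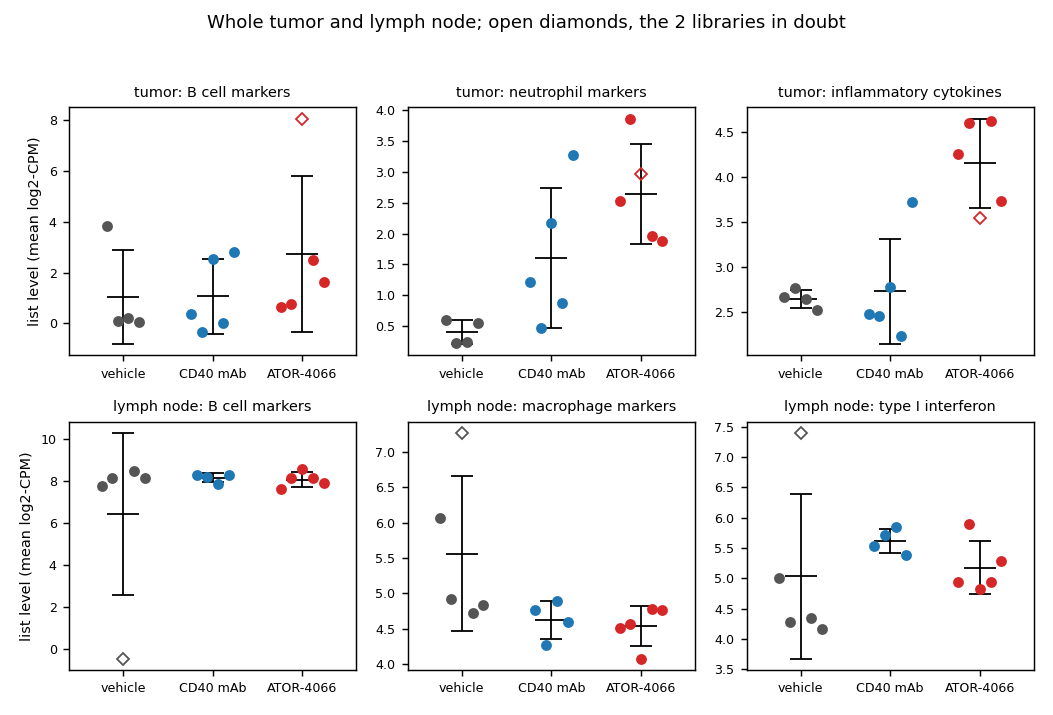
Mean log2-CPM of gene lists in each whole tumor and lymph node library by treatment, 1 point per library, with bars for the mean and SD of each group and open diamonds for the library labelled tumor ATOR-4066 3 and the library labelled lymph node vehicle 3. B cell markers of the former lie at 8.07, against 0.64 to 2.49 in the other ATOR-4066 tumors.

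In blood, CD40 mAb against vehicle gave the largest count of called genes, 4219 of 12184 (2710 higher, 1509 lower). Type I interferon-induced genes rose in 18 of 19, and in 18 adjusted over the list alone (median 2.86, or 0.75 with scaling to the total count alone, camera adjusted p = 2.26e-07, adjusted p = 0.539 with an estimated correlation). Rsad2, the antiviral protein viperin (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), rose by 4.05 ± 0.57 (SE), from 468 ± 104 to 7770 ± 4750 CPM (SD, n = 5 each, adjusted p = 0.000112). Isg15 rose by 5.58 ± 0.80 and Irf7 by 4.19 ± 0.62, and all of them were above every vehicle library in 5 of 5. Neutrophil markers rose in 16 of 16 (median 1.97, or -0.01 with scaling to the total count alone, camera adjusted p = 5.24e-07, adjusted p = 0.539 with an estimated correlation). Ly6g, the neutrophil surface marker, rose by 3.70 ± 0.66, Ltf by 3.54 ± 0.60 and S100a9 by 2.29 ± 0.43. Erythroid markers rose in 13 of 13 (median 2.42, or 0.43 with scaling to the total count alone, camera adjusted p = 4.65e-06, adjusted p = 0.539 with an estimated correlation). The red cell membrane gene Epb42 rose by 4.29 ± 0.56. Haemoglobin genes took 79.5 ± 1.59 percent of counts against 73.9 ± 2.44 in vehicle (SD). B cell markers fell in 13 of 14 (median -0.91, or -2.52 with scaling to the total count alone, camera adjusted p = 2.26e-07, adjusted p = 0.539 with an estimated correlation). Cd79b, part of the B cell receptor (ENSMUSG00000040592, chromosome 11, 106311341 to 106314762), had a change of -0.99 ± 0.21 (45.1 ± 4.56 to 22.7 ± 8.77 CPM, adjusted p = 0.00157) and Pax5 of -1.03 ± 0.21, each below every vehicle library in 5 of 5. MHC class II genes fell in 9 of 11 (median -0.78, camera adjusted p = 1.38e-05, adjusted p = 0.539 with an estimated correlation), with Cd74 at -0.96 ± 0.23. T cell markers had 1 of 18 called and 0 adjusted over the list alone (median -0.07, or -1.81 with scaling to the total count alone, camera adjusted p = 0.874).

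With scaling to the total count alone, which moved the median of all genes by -1.67, the medians of further lists of the same blood comparison lay below 0 but above that shift of all genes. Interferon-gamma-induced genes rose in 15 of 16 (median 1.65, or -0.37 with that scaling, camera adjusted p = 5.24e-07) and proliferation genes in 10 of 17 (1.46, or -0.35, 4.65e-06), each with an adjusted p = 0.539 with an estimated correlation. So did platelet markers in 11 of 12 and 12 adjusted over the list alone (1.02, or -0.87, 2.17e-05), MHC class I genes in 6 of 13 and 8 adjusted over the list alone (0.44, or -1.37, 0.00461) and cytotoxic genes in 5 of 11 and 6 adjusted over the list alone (0.35, or -1.41, 0.0189). Each had an adjusted p = 0.539 with an estimated correlation. Among them Mki67, a marker of cycling cells, rose by 2.51 ± 0.33 (SE) and the GTPase gene Igtp by 3.11 ± 0.50. Treml1, a platelet receptor, rose by 1.71 ± 0.30 (or -0.20 with that scaling) and B2m, the light chain of MHC class I, by 1.79 ± 0.33 (or -0.19). The largest rise was of Atf5, a stress-response transcription factor, by 6.47 ± 0.82 (2.05 ± 0.223 to 182 ± 142 CPM, SD, n = 5 each, adjusted p = 0.000112), with Asns and Mthfd2, genes of amino acid and folate metabolism, up by 5.86 ± 0.80 and 4.98 ± 0.72. With scaling to the total count alone 10972 genes were called, 318 higher and 10654 lower. CD40 mAb 1 lay near the vehicle libraries, with a type I interferon level of 2.45 against 2.21 to 3.02 in vehicle and 4.75 to 6.65 in the other CD40 mAb libraries.

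**Figure D3:**
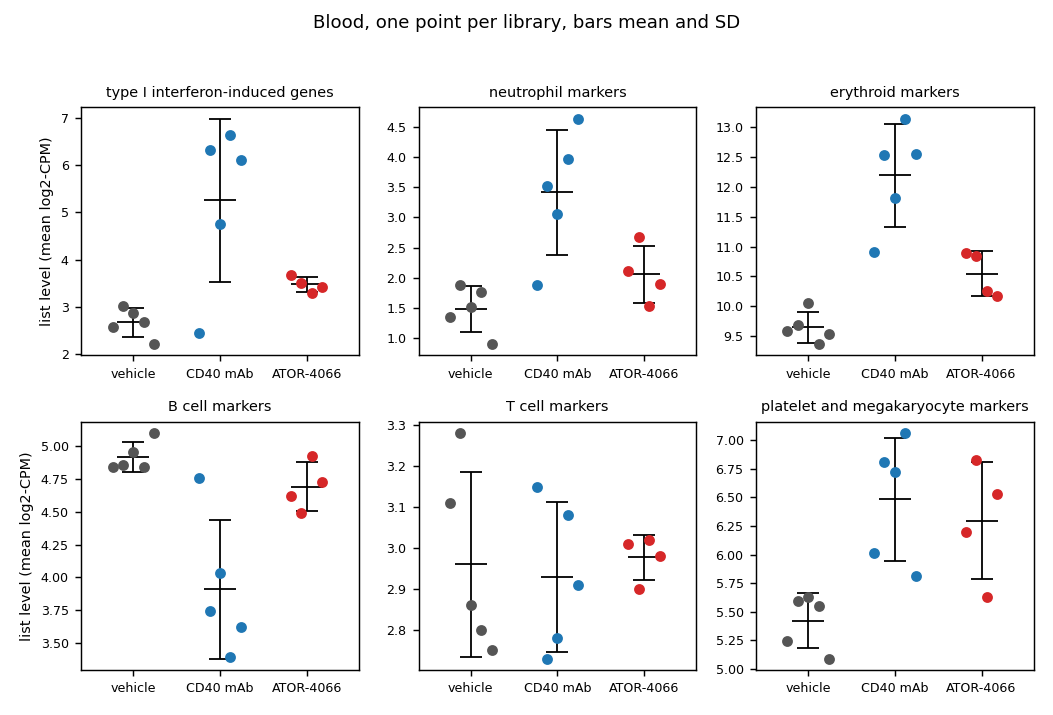
Mean log2-CPM of 6 gene lists in each blood library by treatment, 1 point per library, with bars for the mean and SD of each group. With the TMM scaling drawn here, type I interferon-induced genes lie at 3.29 to 3.67 in the 4 ATOR-4066 libraries, above the 2.21 to 3.02 of the 5 vehicle libraries, while with scaling to the total count alone that median change is -0.28.

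For ATOR-4066 against vehicle in blood, edgeR called few genes, 53 of 12184. Yet 1831 had an unadjusted p under 0.05, and DESeq2 and limma-voom called more. Treml1 (ENSMUSG00000023993, chromosome 17, 48359916 to 48367176) rose by 1.55 ± 0.31 (SE), from 19.3 ± 3.45 CPM (SD, n = 5) to 56.8 ± 27.2 CPM (n = 4, adjusted p = 0.0356, above every vehicle library in 4 of 4). Platelet markers rose together, 1 of 12 over all genes and 12 adjusted over the list alone (median 0.86, or -0.23 with scaling to the total count alone, camera adjusted p = 4.44e-10, adjusted p = 0.517 with an estimated correlation). Morrbid, a long noncoding RNA of myeloid cell survival, rose by 2.08 ± 0.37 and Clec2d by 1.90 ± 0.33. Tnfaip3 and the immediate early gene Jun fell, with changes of -0.77 ± 0.12 and -0.83 ± 0.18 (adjusted p = 0.0153 and 0.0494, below every vehicle library in 4 of 4), and the immediate early list ranked lower (1 of 15 lower, 6 lower and 1 higher adjusted over the list alone, median -0.50, camera adjusted p = 0.00051, adjusted p = 0.517 with an estimated correlation). Type I interferon-induced genes were positive in 19 of 19 with 0 called (median 0.77, or -0.28 with scaling to the total count alone, camera adjusted p = 0.000867, adjusted p = 0.654 with an estimated correlation). Neutrophil, erythroid and endothelial markers ranked higher (0 called each, 0, 2 and 4 adjusted over the list alone, medians 0.70, 0.90 and 0.78, or -0.43, -0.17 and -0.29 with scaling to the total count alone, camera adjusted p = 0.00524 each, adjusted p = 0.654 with an estimated correlation). edgeR called 53 genes, 50 higher and 3 lower, against 428 by DESeq2 and 1011 by limma-voom with sample weights. The count was 0, 12, 6, 1 and 0 without vehicle 1, 2, 3, 4 and 5, 7 without ATOR-4066 3 and 106 without ATOR-4066 4. The neutrophil median was 0.45 without ATOR-4066 3, and the erythroid median 0.59 without ATOR-4066 1. With scaling to the total count alone 9172 genes were called, 11 higher and 9161 lower, the median of all genes moving by -1.03.

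Between the drugs, blood of ATOR-4066 animals had lower interferon, neutrophil and erythroid genes and higher B cell genes than blood of CD40 mAb animals. The haemoglobin share ran the other way, 83.4 ± 4.56 percent of counts against 79.5 ± 1.59 (SD). Isg15 dropped by 4.54 ± 0.84 (SE), from 2910 ± 2560 CPM (SD, n = 5) to 125 ± 48.3 CPM (n = 4, adjusted p = 0.00526, below every CD40 mAb library in 2 of 4), and Rsad2 by 3.37 ± 0.61. Type I interferon-induced genes fell in 12 of 19, 16 adjusted over the list alone (median -2.04, camera adjusted p = 3.83e-06), and interferon-gamma-induced genes in 11 of 16, 13 adjusted over the list alone (-1.25, 1.32e-06), each with an adjusted p = 0.488 with an estimated correlation. Neutrophil markers fell in 7 of 16, 10 adjusted over the list alone (-1.48, 3.83e-06), erythroid markers in 9 of 13, 12 adjusted over the list alone (-1.63, 9.68e-06), and proliferation genes in 8 of 17, 10 adjusted over the list alone (-1.04, 2.15e-06), each with an adjusted p = 0.488 with an estimated correlation. Ltf, Epb42 and Mki67 had changes of -3.02 ± 0.67, -3.40 ± 0.59 and -2.05 ± 0.36. B cell markers rose in 6 of 14, 13 adjusted over the list alone (median 0.71, 5.54e-08), with Cd79b up by 0.79 ± 0.21, and MHC class II genes in 6 of 11, 10 adjusted over the list alone (0.63, 4.01e-06). Both had an adjusted p = 0.488 with an estimated correlation. With scaling to the total count alone the medians were -1.06 for type I and -0.31 for interferon-gamma-induced genes, -0.65 for neutrophil and -0.73 for erythroid markers, -0.31 for proliferation genes and 1.25 for B cell markers. edgeR called 1593 genes, 281 higher and 1312 lower, or 17.6 percent higher. The count was 832 when only these groups were fitted (6.37 percent higher), 3026 without CD40 mAb 1 (33.5 percent higher), and 914 and 1003 without ATOR-4066 4 and 5. With scaling to the total count alone 2707 genes were called, 2324 higher and 383 lower, the median of all genes being 0.65 higher.

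In lymph node no gene passed in any comparison. With ATOR-4066 against vehicle, plasma cell and germinal center genes ranked higher (2 of 19 adjusted over the list alone, median 1.06, camera adjusted p = 0.000314, adjusted p = 0.502 with an estimated correlation). Xbp1, the secretory factor of plasma cells (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893), was at 568 ± 236 CPM against 273 ± 101 CPM (SD, n = 5 each), a change of 1.06 ± 0.31 (SE, adjusted p = 0.223, above every vehicle library in 5 of 5). Prdm1, which drives plasma cell formation, had a change of 0.95 ± 0.27. Without the library labelled lymph node vehicle 3, 7 of 19 members of the plasma cell list were higher adjusted over the list alone (median 0.76). Macrophage markers (15 of 18 lower adjusted over the list alone, median -1.11, camera adjusted p = 4.00e-06) and fibroblast genes (8 of 16 lower, median -1.21, 3.51e-05) ranked lower, each with an adjusted p = 0.464 with an estimated correlation. Without the library labelled lymph node vehicle 3 these medians were -0.44 and -0.48, and 1 and 3 members were lower adjusted over the list alone. Skeletal muscle, skin and fat genes ranked lower too (2 of 11 adjusted over the list alone, median -1.42, camera adjusted p = 0.00665, adjusted p = 0.503 with an estimated correlation) as did tumor epithelial markers (0 of 14, -0.64, 0.0264, adjusted p = 0.692 with an estimated correlation). Without that library their medians were -1.36 and -0.94. Erythroid markers ranked lower (1 of 10 adjusted over the list alone, median -1.65, camera adjusted p = 0.00665, adjusted p = 0.503 with an estimated correlation), with 8 of 10 lower adjusted over the list alone without that library. Adipoq, a fat cell gene chosen after its values were seen, was at 119.8 to 321.1 CPM scaled to the total count in the other vehicle lymph nodes and at 1.004 to 1.378 CPM in ATOR-4066 2, 3 and 4, but at 160.2 and 167.9 CPM in ATOR-4066 1 and 5. Type I interferon-induced genes went without that library from a median of -0.38 (0 of 19 adjusted over the list alone, camera adjusted p = 0.503) to 0.76 (15 of 19, camera adjusted p = 2.51e-12, adjusted p = 0.38 with an estimated correlation). T cell markers ranked higher (0 of 18, median 0.45, camera adjusted p = 0.000425, adjusted p = 0.588 with an estimated correlation), with a median of 0.13 without that library. edgeR called 0 of 18763 genes, with 2997 at an unadjusted p under 0.05, DESeq2 called 615 and limma-voom with sample weights 4.

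CD40 mAb against vehicle in lymph node ranked MHC class I and proliferation genes higher, while MHC class II genes did not pass (median 0.14, camera adjusted p = 0.277). Plasma cell and germinal center genes ranked higher, as with ATOR-4066 (0 of 19 adjusted over the list alone, median 1.07, camera adjusted p = 0.0024, adjusted p = 0.631 with an estimated correlation). Without the library labelled lymph node vehicle 3, 8 of them were higher and 2 lower adjusted over the list alone (median 0.82). Macrophage markers ranked lower, as with ATOR-4066 (8 of 18 adjusted over the list alone, median -0.76, camera adjusted p = 0.000133). So did fibroblast genes (6 of 16, median -1.01, 9.99e-05), each with an adjusted p = 0.631 with an estimated correlation. Without that library these medians were -0.38 and -0.41, with 3 and 0 members lower adjusted over the list alone. All 13 MHC class I genes were positive, 7 adjusted over the list alone (median 0.30, camera adjusted p = 2.96e-06), and so were all 20 proliferation genes, 0 adjusted over the list alone (median 0.52, 6.86e-07), each with an adjusted p = 0.631 with an estimated correlation. Without the library labelled lymph node vehicle 3, 13 and 20 of these passed adjusted over the list alone, the proliferation median was 0.87, and interferon-gamma-induced genes went from 0 to 13 higher and 1 lower of 21. H2-K1, a class I heavy chain, was at 3560 ± 206 CPM (SD, n = 4) against 2860 ± 151 CPM (n = 5), a change of 0.32 ± 0.08 (SE). Ccnb2, a mitotic cyclin, had a change of 0.87 ± 0.26, and neither passed (adjusted p = 0.226 each, above every vehicle library in 4 of 4). Cd209a, a lectin of monocyte-derived dendritic cells, had the smallest p, with a change of -3.71 ± 0.53 (adjusted p = 0.0844, 4 of 4 lower). The type I interferon-induced list had a median of -0.08 and a mean of -0.11 while camera ranked it higher (0 of 19 adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.701 with an estimated correlation). Without the library labelled lymph node vehicle 3, whose level of these genes was 7.39 against 4.16 to 5 in the other vehicle lymph nodes, the median was 1.11 (1 called, 19 of 19 adjusted over the list alone, camera adjusted p = 3.06e-17, adjusted p = 0.604 with an estimated correlation). edgeR called 0 genes, with 3145 at an unadjusted p under 0.05, and 12 without that library (9 higher, 3 lower). DESeq2 called 688 and limma-voom with sample weights 1299.

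ATOR-4066 against CD40 mAb in lymph node ranked proliferation genes lower, negative in 20 of 20 with 0 passing adjusted over the list alone (median -0.52, camera adjusted p = 7.96e-13, adjusted p = 0.49 with an estimated correlation). Without the library labelled lymph node vehicle 3, 17 passed adjusted over the list alone. Erythroid markers ranked lower (2 of 10 adjusted over the list alone, median -1.43, camera adjusted p = 6.37e-10), as did neutrophil markers (0 of 14, median -0.47, 0.00012), each with an adjusted p = 0.202 with an estimated correlation. MHC class I genes (0 of 13, median -0.18, camera adjusted p = 2.89e-06) and interferon-gamma-induced genes (0 of 21, median -0.36, 0.000391) ranked lower, with adjusted p = 0.49 and 0.945 with an estimated correlation. Plasma cell and germinal center genes did not pass (median 0.04, camera adjusted p = 0.649). Cd209a was at 5.61 ± 1.74 CPM (SD, n = 5) against 0.616 ± 0.350 CPM (n = 4), a change of 3.18 ± 0.52 (SE, adjusted p = 0.631, 5 of 5 higher). edgeR called 0 genes, with 496 at an unadjusted p under 0.05, DESeq2 called 21 and limma-voom with sample weights 2.

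The responses to the drugs against their shared vehicle libraries were compared across genes, which are not independent replicates. The simulated unchanged groups were drawn, vehicle included, from a common mean per gene and independently between genes. They hold neither the real correlation between genes nor a library with the profile of another tissue. An observed value above the simulated one is therefore not by itself a shared response. In sorted cells the fold changes had a correlation of 0.340 and a covariance of 0.408, against 0.413 and 0.196 in simulated unchanged groups. The drugs shared 42 higher and 55 lower genes where independent lists would share 6.01 and 4.75, a value that leaves the shared vehicle libraries out of account. In blood the values were 0.63 and 0.252 against a simulated 0.413 and 0.0362, with 42 shared higher genes and 0 lower where independent lists would share 11.1 and 0.372. In tumor they were 0.63 and 0.390 against 0.561 and 0.153, and in lymph node 0.847 and 0.448 against 0.470 and 0.105. With the vehicle libraries divided in 2 parts, 1 for each drug, the mean correlations were 0.146 in sorted cells, 0.510 in blood, 0.484 in tumor and 0.366 in lymph node. With those smaller groups the mean counts of shared genes were 0.167 higher and 0.167 lower in sorted cells, of 179.8 and 164.7 called with ATOR-4066 and 11.5 and 46.5 with CD40 mAb. In blood they were 0.15 higher and 0 lower, of 0.2 and 0.05 called with ATOR-4066, and no gene was shared in tumor or lymph node. Without the doubted library the correlation and covariance were 0.701 and 0.347 in tumor and 0.774 and 0.253 in lymph node.

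Whether a drug's effect differed between tissues was tested with an interaction term over 20473 genes, and the genes named here beyond the lists were chosen after their values were seen. The CD40 mAb effect differed between tumor and blood in 1521 genes, 414 higher and 1107 lower in tumor. Among these were 8 of 19 type I interferon-induced genes (14 adjusted over the list alone, median difference -2.73), 8 of 21 interferon-gamma-induced genes (15 adjusted over the list alone, -1.81) and 10 of 20 proliferation genes (13 adjusted over the list alone, -2.11), all lower in tumor. These rest on TMM scaling of blood and were not tested with scaling to the total count alone, under which the blood medians of the interferon-gamma and proliferation lists were -0.37 and -0.35 and the median of all genes moved by -1.67. Between lymph node and blood the CD40 mAb effect differed in 3346 genes, 1293 higher and 2053 lower in lymph node. There 3 of 11 MHC class II genes were higher (7 adjusted over the list alone, median difference 1.21), 4 of 13 erythroid markers lower (6 adjusted over the list alone, -1.74) and 4 of 19 type I interferon-induced genes lower (6 adjusted over the list alone, -1.37, and -0.81 without both doubted libraries). These differences, and those of ATOR-4066 from blood below, also rest on TMM scaling of blood and were not tested with scaling to the total count alone. Under that scaling the CD40 mAb blood medians were 0.43 in place of 2.42 for erythroid markers and 0.75 in place of 2.86 for type I interferon-induced genes. Between tumor and lymph node the CD40 mAb effect differed in 0 genes by limma (2361 at an unadjusted p under 0.05), in 5 by edgeR without the animal block and in 834 without both doubted libraries. Proliferation genes had a median difference of -1.59, with 19 of 20 lower in tumor adjusted over the list alone. The ATOR-4066 effect differed between tumor and blood in 100 genes, 50 in each direction, with 2 of 15 NF-kappaB targets higher in tumor and 9 adjusted over the list alone (median difference 0.78). These were Tnfaip3 by 1.68 ± 0.27 (SE, adjusted p = 0.00347) and Nfkbia by 1.15 ± 0.20 (adjusted p = 0.00834). It differed in 22 genes between lymph node and blood, 5 higher and 17 lower, with Tnfaip3 higher by 1.26 ± 0.24 (adjusted p = 0.0176), and in 18 between tumor and lymph node, 16 higher and 2 lower. Among the last were Clec4e, a lectin receptor of activated myeloid cells (4.05 ± 0.74), and the lipid droplet gene Plin2 (2.79 ± 0.50, adjusted p = 0.0104 each). Without both doubted libraries the tumor and lymph node count was 1639, by edgeR without the animal block 251 and without sample weights 168. By edgeR and without sample weights, the ATOR-4066 counts were 242 and 37 between tumor and blood and 107 and 11 between lymph node and blood. The CD40 mAb counts were 2200 and 923 between tumor and blood and 3005 and 1250 between lymph node and blood.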

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

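All tests of explanations in this part were chosen after the result they bear on was seen, while the interactions between tissues and the splits of the samples were planned. The rule by which the splits were read was written afterwards. Of 90 combinations of group and measure, 9 held a library far from the others of its group, and chance flags about 1 in 20 groups.

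The library labelled lymph node vehicle 3 had Ptprc at 218 CPM (812 to 1050 in the other vehicle lymph nodes), T cell markers at a mean log2-CPM of 3.28 (6.85 to 7.47), B cell markers at -0.46 (7.77 to 8.45) and type I interferon-induced genes at 7.39 (4.16 to 5). The library labelled tumor ATOR-4066 3 had B cell markers at 8.07 (0.64 to 2.49) and 67.62 M counts (47.44 to 52.49). In the former, genes specific to lymph node were at 0.25 percent of their level in the other lymph nodes, which argues against lymph node tissue mixed with tumor, and genes specific to tumor were at 103 percent, so a whole tumor library under this label may explain it. No library is labelled as the tumor of vehicle animal 3, and whether this one is that animal's own tumor was not tested. In the latter, tumor-specific genes were at 6.03 percent and genes specific to lymph node at 87.9 percent (73.8 to 118 in the lymph nodes), which leaves a mixture with lymphoid tissue and another tissue's library open. A swap of these libraries with each other cannot be told apart from separate errors, since only 1 gene, Capn11, was informative on the animal. It read like the labelled animal, which goes against a swap, but 1 gene is too few to decide, and no biological explanation was tested.

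In tumor vehicle 1, B cell markers were at 3.83 against 0.06 to 0.22 in the other vehicle tumors. Total counts were 44.08 M in blood vehicle 1 (35.13 to 35.57 in the others) and 138.5 M in lymph node ATOR-4066 5 (50 to 58.07).

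In blood of CD40 mAb animals, interferon, neutrophil and erythroid genes were higher and B cell genes lower than in vehicle. The type I interferon median was at least 0.75 over 5 scalings. It was 2.83 to 2.87 with TMM, DESeq2-type size factors, DESeq2 or haemoglobin and receptor segment genes left out. Only scaling to the total count gave 0.75 (14 of 19 above 0, 10 called higher and 2 lower). The size of the rise therefore rests on the scaling, but its sign did not change. That argues against TMM scaling as the whole cause for the type I list. For interferon-gamma-induced genes the median with scaling to the total count was -0.37 while that of all genes moved by -1.67, and the explanation was not tested for them. Neutrophil minus B cell markers differed by 2.88 (spread 0.79), so these kinds did not shift alike. That contrast is part of the pattern first seen, so it is no separate test of fewer white cells of all kinds. For the erythroid genes, the same red cells among fewer white cells cannot be told apart from more young red cells, because erythroid markers exceeded haemoglobin genes by 0.74 with a spread of 0.89. A response of blood cells to CD40 mAb may therefore underlie the type I interferon-induced genes, as a hypothesis found and tested on the same data.

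In sorted cells of ATOR-4066 animals, T cell markers were higher and macrophage, type I interferon and fibroblast genes lower. T cell minus macrophage markers differed by 2.62 (spread 1.84), so these leukocyte genes did not shift alike. That contrast is part of the pattern first seen, so it is no separate test of less stromal carry-over alone. The T cell median was 1.5 without ATOR-4066 9, which argues against that B-cell-rich library alone as the source of the higher T cell markers. The type I interferon and fibroblast medians were then -1.09 and -1.76. The macrophage median was -0.34 in place of -0.79, so the lower macrophage markers, and the difference from T cell markers above, rest in part on that library. The T cell markers moved nearly alike, with an interquartile range of 0.38, so a shift in cell makeup toward T cells, whether biological or from the sort, may explain them.

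Genes were called in 5 of 6 interactions between tissues. For ATOR-4066 the counts were 18 genes between tumor and lymph node, 100 between tumor and blood and 22 between lymph node and blood, and for CD40 mAb 1521 between tumor and blood and 3346 between lymph node and blood. Of 25 splits of the libraries, 1, the real one, gave as many genes for ATOR-4066 in tumor against blood (highest other 1) and in lymph node against blood (2), and for CD40 mAb in tumor against blood (2) and in lymph node against blood (1099). These 25 are a part of the 126 possible splits, so they make chance less likely there but do not exclude it. For ATOR-4066 in tumor against lymph node 2 of 25 gave as many (highest other 111), so chance cannot be excluded, and that split points to a structure of the samples. A smaller draw of splits held no other split as large, so this verdict depends on the draw. For CD40 mAb in tumor against lymph node the count was 0 (limma, 2361 at an unadjusted p under 0.05, 5 by edgeR, 834 without both doubted libraries), all 25 gave as many, and the highest other was 1.

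Within tissues, no other split gave as many genes as the 1977 and 182 in sorted cells against vehicle (1 of 35 splits, the real one, highest other 1 in each). Chance is therefore less likely as the source of these counts. Yet 1 of 35 is the smallest share these splits can reach, and it was not adjusted over the comparisons. In blood, of 100 splits only the real one gave as many as the 53 and 4219 genes against vehicle (highest other 1 and 3590), so chance is less likely there. For the 1593 genes between the drugs 4 of 100 gave as many (highest other 3408), so chance cannot be excluded. The 3590 and the 3408 point to a structure of the samples. For 1372 genes between the drugs in sorted cells the 10 splits are too few, and the highest other was 0. In tumor and lymph node the real counts were 0, so all 100 splits were as large. Their highest counts were 89, 1 and 2291 in tumor and 7, 1 and 60 in lymph node for ATOR-4066 against vehicle, CD40 mAb against vehicle and ATOR-4066 against CD40 mAb. The 2291 and the 89 point to a structure of the samples that does not follow the groups.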

How the results depend on the processing

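The fits without the doubted libraries and the blood fit scaled to the total count alone were chosen after seeing the data, and the other alternatives were planned. Where a cause is not named below, the cause was not tested. In each triple, counts are for ATOR-4066 against vehicle, CD40 mAb against vehicle and ATOR-4066 against CD40 mAb. Of the recomputed counts of genes 66 stayed within 1.5 times, 33 were higher and 6 lower, and with one library left out 74, 8 and 22. DESeq2 gave 1773, 21 and 184 in tumor, 3423, 1465 and 2960 in sorted cells, 615, 688 and 21 in lymph node, and 428 for ATOR-4066 against vehicle in blood. Sample weights gave 5043, 1 and 449 in tumor, 4484, 686 and 2111 in sorted cells, 4, 1299 and 2 in lymph node, and 1011 for ATOR-4066 against vehicle in blood. Fitting only the groups compared gave 1315 for ATOR-4066 against vehicle in tumor, 732 for CD40 mAb against vehicle and 3 between the drugs in sorted cells, and 1062 and 832 for ATOR-4066 against vehicle and against CD40 mAb in blood. No filter gave 391 for CD40 mAb against vehicle in sorted cells. Replicate numbers do not pair the libraries (47 pairs, median correlation 0.004, and not every sample correlated best with its own number). With that block the counts were 3059 for ATOR-4066 against vehicle in tumor, 216, 91 and 119 in sorted cells, and 713 for ATOR-4066 against vehicle and 0 between the drugs in blood (edgeR). Without the doubted library they were 243, 0 and 6 in tumor and 0, 12 and 3 in lymph node. With one library left out they ranged from 0 to 243 and 0 to 103 for ATOR-4066 in tumor, 627 to 2525, 2 to 272 and 105 to 2422 in sorted cells, 0 to 12 for CD40 mAb in lymph node, and 0 to 106, 3434 to 5433 and 914 to 3026 in blood. Blood scaled to the total count gave 9172, 10972 and 2707, the median of all genes moving by -1.03, -1.67 and 0.65.

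Of the interactions, edgeR without the animal block gave 251 for ATOR-4066 and 5 for CD40 mAb in tumor against lymph node, and 242 and 107 for ATOR-4066 in tumor and in lymph node against blood. Without sample weights they were 168 for ATOR-4066 in tumor against lymph node, 37 and 11 for ATOR-4066 in tumor and in lymph node against blood, and 923 and 1250 for CD40 mAb. Without both doubted libraries they were 1639 and 834 in tumor against lymph node and 160 for ATOR-4066 in lymph node against blood.

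Of 342 list tests 146 passed with the preset correlation, 0 with an estimated one (camera of limma). Without the doubted libraries 2 passed with an estimated correlation. These were inflammatory genes and immediate early and heat shock genes in tumor between the drugs (camera adjusted p = 0.039 each). Among lists that passed, medians changed sign as follows. With sample weights, B cell markers were at -0.04 in tumor between the drugs and at -0.11 and -0.1 in lymph node for ATOR-4066 and CD40 mAb against vehicle, where type I interferon-induced genes were at 1.32 and macrophage markers at 0.02 for CD40 mAb. With the block by number the former were at 0.71. Without the doubted library, B cell markers were at -0.7 in tumor for ATOR-4066 against vehicle and at -0.19 between the drugs, with T cell markers at -0.48. In lymph node B cell markers were then at -0.09 for ATOR-4066 and -0.01 for CD40 mAb, with type I interferon-induced genes at 1.11 and T cell markers at -0.15 for CD40 mAb. With one library left out, medians ranged from -0.7 to 6.46 for B cell markers in tumor for ATOR-4066 against vehicle. Between the drugs in tumor they ranged from -0.19 to 5.52 for B cell markers, -0.48 to 2.25 for T cell markers, -0.22 to 1.6 for cytotoxic genes and -0.01 to 1.26 for checkpoint genes. In sorted cells they ranged from -0.01 to 3.42 for B cell markers with ATOR-4066 against vehicle. In lymph node they ranged from -0.09 to 0.46 for B cell markers with ATOR-4066, and with CD40 mAb from -0.31 to 1.11 for type I interferon-induced genes, -0.01 to 0.71 for interferon-gamma-induced genes, -0.15 to 0.38 for T cell markers and -0.01 to 0.52 for B cell markers. In blood scaled to the total count, ATOR-4066 against vehicle gave -0.64 for interferon-gamma-induced genes, -0.28 for type I interferon-induced genes, -0.7 for proliferation genes, and -0.43, -0.17, -0.23 and -0.29 for neutrophil, erythroid, platelet and endothelial markers. CD40 mAb against vehicle gave -0.37 for interferon-gamma-induced genes, -1.37 for MHC class I genes, -1.41 for cytotoxic genes, -0.35 for proliferation genes, and -0.01 and -0.87 for neutrophil and platelet markers. Treml1 was then at -0.2, Gp9 at -0.43, B2m at -0.19 and Cd28 at -1.49. Between the drugs MHC class I genes were at 0.62 and immediate early genes at 0.12.

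Of 77 called named genes in sorted cells, DESeq2 called 77, no filter 55 and the block by number 28 of 76, and of 46 in blood these called 46, 43 and 31. With one library left out none of these changed sign, but calls were lost, with 8 of 33 still called without sorted CD40 mAb 10 and 30 of 55 without sorted vehicle 10. On simulated data, 4-fold changes were recovered in 48 to 73 percent of genes in tumor, sorted cells and lymph node, so genes without a call there are not shown to be unchanged.

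With the vehicle libraries divided in 2 parts, the correlations between the responses to both drugs were 0.4836 in tumor, 0.146 in sorted cells, 0.366 in lymph node and 0.5103 in blood.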

Other observations

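No further hypothesis was tested for this part, and the values here were chosen after they were seen. Ptprc, which encodes the leukocyte surface protein CD45, passed in none of the 3 comparisons of sorted cells, with 1510 ± 135 CPM in vehicle (SD, n = 4) and a change of 0.04 ± 0.15 with ATOR-4066 (SE, adjusted p = 0.895). In blood, scaled to the total count, Ptprc averaged 294.8 CPM in vehicle, 81.04 with CD40 mAb and 124.9 with ATOR-4066. On the same scale Cd8a averaged 18.6, 5.40 and 8.47 CPM. With TMM scaling Cd8a did not pass in blood, with changes of -0.06 ± 0.12 for CD40 mAb and -0.07 ± 0.13 for ATOR-4066 (adjusted p = 0.738 and 0.848).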
